A study of Mus musculus with 12 samples.

How the data were processed

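RNA was measured in 12 whole mouse embryos from timed matings of animals heterozygous for Mfsd12, collected between 10.0 and 11.0 days after fertilization. Mfsd12 encodes a membrane protein of lysosomes and melanosomes that is required for cysteine import into these organelles. Per the labels' protocols, libraries were made from 325 ng of total RNA with a strand-marking mRNA kit, and spike-in RNA was added. Per the labels, 4 embryos were knockout, 4 heterozygous and 4 wild-type. Each embryo is a separate animal. The labels give no replicate numbers, so embryos were numbered within a genotype in deposition order, and the numbers pair nothing.

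The authors deposited 1 table of estimated counts per gene (expected counts, not normalized). Per the file headers, it was made with featureCounts 2.0.6 against the RefSeq annotation of GRCm39. Reads that mapped to several places or overlapped several genes added fractions of a read, each mate of a pair was counted on its own, and strand was not used. An antisense gene therefore shares reads with its partner, and near-identical genes such as the alpha globins share theirs. DRAGEN is named in the submitters' processing notes without a role. The table held 41079 genes and 0 rows of spike-in RNA, so the planned scaling to spike-ins and the planned comparison of their share could not be run.

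Totals lay between 53133084 and 67977990 counted reads per embryo. No pair of libraries agreed within sampling noise. Estimated counts were rounded to whole numbers. Genes with too few counts were removed with filterByExpr, which left 20771 genes, and libraries were scaled by TMM factors. The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, a mean per genotype and all 12 embryos in the fit. P-values were two-sided and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes were obtained from the fold change and its F statistic. CPM values, counts scaled to a common library total, use the TMM-scaled totals and are given as mean ± SD. The comparisons were knockout against wild-type, knockout against heterozygous, heterozygous against wild-type, and knockout against the mean of the other 2 genotypes.

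Of 43 gene lists fixed before the data were examined, 42 were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2), with the correlation between genes preset at 0.01 and adjustment over the 42 lists. The plan named a camera method for count objects as well as log2 CPM; log2 CPM was used, and the count-model version was run as an alternative. Each list also has a score per embryo, the mean over its genes of the log2 CPM centred on the mean of the 12 embryos, compared by an exact two-sided permutation test that was added after seeing the data. With 4 embryos against 4, the smallest p such a test can give is 0.0286. A stage index was the mean z score, over the 12 embryos, of genes that are higher later in development minus that of genes that are lower later. The index comes from gene expression alone, and the labels give no stage per embryo. Its genes include members of the neuronal, erythroid, somite, skeletal muscle and hepatoblast lists. A stage index covariate therefore shrinks the differences of those lists, and of the stage lists themselves, in part by construction.

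Mfsd12 was always to be named. The rule for other genes took those past the adjusted threshold, and 0 genes passed for the 3 pairs of genotypes. List members were then taken by their p-value adjusted over the list alone, up to 4 per list, or as the 2 most abundant. Chac1 and all other genes outside these parts were chosen after their values were seen. These were mainly Atf5, Tektip1, Car4, Plet1, Prdm1, Gli1, Slc1a4, Kif1a, Ucp2, Nppa and Ap3b2.

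Alternatives were DESeq2 1.42.0, limma voom with sample weights, other scalings and count filters, fits of the compared groups alone, and covariates for the first number in each title, for Xist and for the stage index. Each embryo was also left out in turn. A covariate for ribosomal RNA reads and a fit without the library labelled heterozygous 2 and knockout 3 were added after seeing the data. The first number in the titles (4, 14, 15, 18 or 4.1b) has no stated meaning. Only 4 and 18 occurred with every genotype.

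The tests were tested on simulated data. Counts were drawn from the means, library sizes and dispersions of the real embryos, with 200 genes changed in knockout embryos, and the 36 ATF4 targets raised 2-fold there as a test of the lists, among 20367 genes that passed the filter. The edgeR test recovered 52% of the 50 genes changed 2-fold, 84% of those changed 4-fold and 98% of those changed 8-fold, and called 9 of 20131 unchanged genes, where DESeq2 called 50 and limma voom 7. The changed genes were drawn only from the more abundant genes, and simulated embryos varied independently, without title numbers. The shares recovered therefore do not carry over to all genes tested or to the real embryos. Figures were drawn with matplotlib 3.10.9.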

Results

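Whole-embryo RNA was compared between Mfsd12 knockout, heterozygous and wild-type mouse embryos, with 4 embryos of each genotype and 53133084 to 67977990 counted reads per embryo. The series title links reduced thiols in lysosomes to embryonic development, and the comparisons ask how expression differed when 1 or both copies of the gene were disrupted.

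Mfsd12 itself was lowest in knockout and highest in wild-type embryos, and the library labelled heterozygous 2 went against its label. The gene lies on chromosome 10 from 81193325 to 81202059 on the plus strand of GRCm39. Its level was 11.9 ± 3.23 CPM in wild-type (SD, n = 4), 5.84 ± 2.56 CPM in heterozygous and 2.97 ± 0.544 CPM in knockout embryos. Knockout embryos had 4.02-fold less than wild-type embryos (log2 fold change -2.01 ± 0.33 SE, edgeR p = 3.71e-05 as a single planned gene, adjusted p = 0.385 over all genes, exact permutation p = 0.0286, the smallest possible). The difference was also present among embryos of title number 4 (log2 difference -1.75) and of title number 18 (-1.996). Heterozygous embryos lay lower than wild-type by a log2 fold change of -1.03 ± 0.32 SE (edgeR p = 0.00684, exact permutation p = 0.0286). Knockout lay lower than heterozygous embryos by -0.98 ± 0.33 SE in edgeR (p = 0.00989), and the exact permutation test missed the threshold (p = 0.114). Without the library labelled heterozygous 2 the last 2 log2 fold changes were -0.79 and -1.22. With Xist or the stage index as a covariate, the edgeR p of knockout against heterozygous rose above the threshold (log2 fold change -0.45 with the stage index). The library labelled heterozygous 2 had 2.58 CPM, inside the knockout range of 2.31 to 3.57 CPM, while the other heterozygous embryos had 5.91 to 8.84 CPM. Tektip1, an antisense gene inside the Mfsd12 span (81199858 to 81201654, minus strand), had 0.516 ± 0.123 CPM in knockout and 1.998 ± 0.611 CPM in wild-type embryos, and its reads cannot be told apart from those of Mfsd12.

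**Figure D1:**
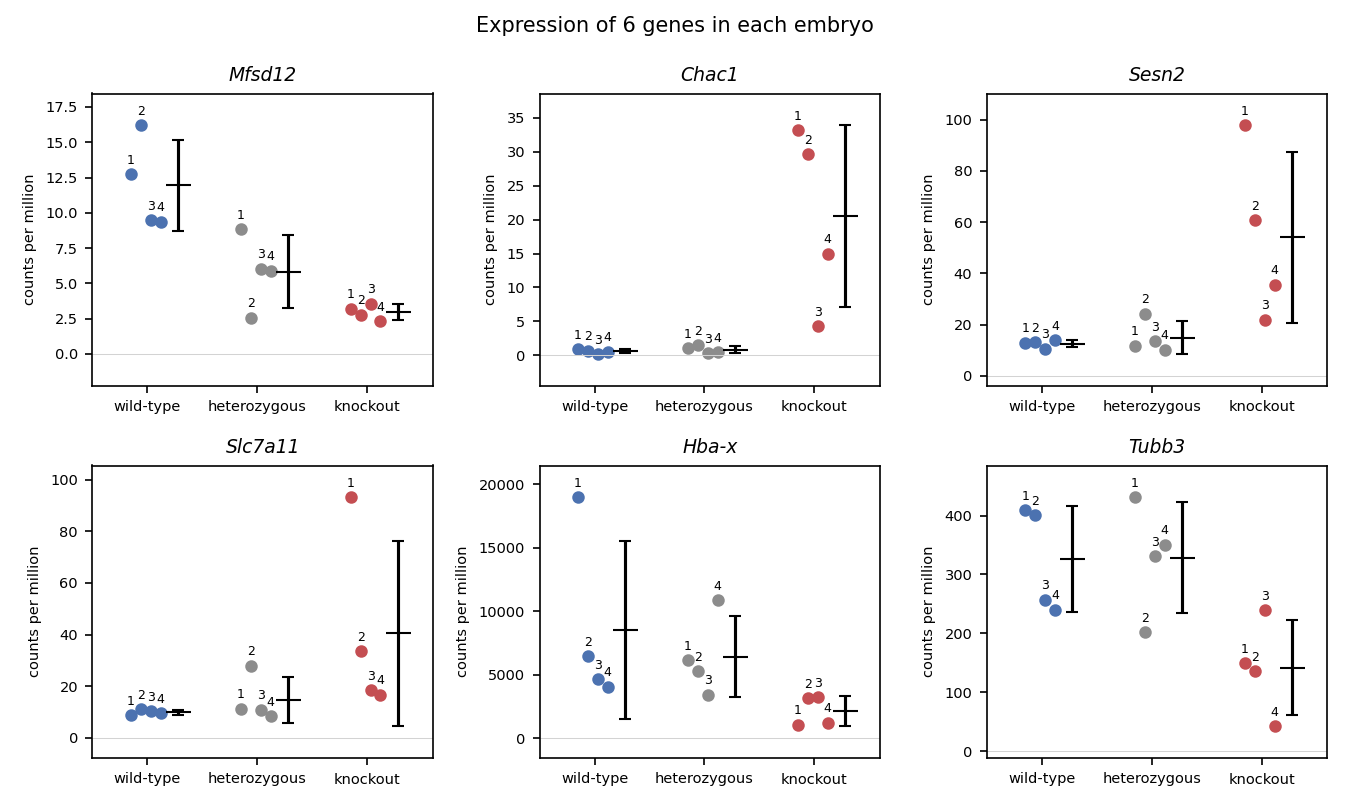
CPM (linear axes) of 6 genes in each of the 12 embryos; points are embryos with their replicate number, and bars are the mean ± SD of 4 embryos. Chac1 lay at 4.28 CPM or more in each knockout embryo and at 1.5 CPM or less in all others.

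In knockout against wild-type embryos, amino acid and stress genes controlled by the transcription factor ATF4 lay higher and red blood cell genes lower. Chac1, an enzyme that degrades glutathione, had 20.5 ± 13.4 CPM in knockout (SD, n = 4) and 0.582 ± 0.286 CPM in wild-type embryos, a 35.2-fold difference. Sesn2, a stress-induced regulator of nutrient signalling, had 54.0 ± 33.3 against 12.6 ± 1.37 CPM. Slc7a11, the cystine and glutamate exchanger, had 40.5 ± 35.9 against 9.83 ± 1.07 CPM, and Slc7a1, a transporter of cationic amino acids, 124 ± 62.6 against 40.4 ± 17.7 CPM. Among the red blood cell genes, the embryonic globin Hba-x had 2136 ± 1181 against 8521 ± 7020 CPM.

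Of the 36 measured ATF4 targets, 34 had a positive fold change in knockout against wild-type embryos. Adjusted over the list alone, 20 rose and 0 fell, and 0 passed over all genes tested. The 4 with the smallest p were Chac1 (log2 fold change 5.14 ± 0.70 SE), Sesn2 (2.10 ± 0.40 SE), Slc7a11 (2.04 ± 0.52 SE) and Slc7a1 (1.62 ± 0.45 SE). Others that rose, adjusted over the list alone, were the transcription factors Atf3, Atf4 and Atf5, the asparagine synthetase Asns, the serine synthesis enzyme Psat1 and the transsulfuration enzyme Cth. Without knockout 1, which had 93.1 CPM of Slc7a11 against 16.7 to 33.6 CPM in the other knockout embryos, the log2 fold changes were 1.22 for Slc7a11, 1.26 for Asns, 0.98 for Cth and 0.59 for Atf5, in place of 2.04, 1.91, 1.83 and 1.56. The list was called by camera (adjusted p = 2.77e-15), but not with its gene correlation estimated from these data (adjusted p = 0.566 with an estimated correlation). Its score (mean centred log2 CPM) was 0.62 ± 0.74 in knockout and -0.55 ± 0.11 in wild-type embryos, and every knockout embryo lay above every wild-type embryo (exact permutation p = 0.0286, the smallest this design can give, and 0.4 after adjustment over the lists). The difference in score was 1.43 within title number 4 and 0.36 within title number 18. Number 14 held no wild-type embryo, and its knockout 1 lay 0.21 above the library labelled heterozygous 2. These 2 embryos had the highest scores of all, 1.53 and 1.33, so the score may also vary with title number.

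All 30 measured erythroid genes had a lower estimate in knockout embryos, and 26 fell adjusted over the list alone, against 0 over all genes tested. Slc4a1, the anion exchanger of the red cell membrane, differed by a log2 fold change of -1.70 ± 0.45 SE. The embryonic alpha-like globin Hba-x differed by -1.996 ± 0.55 SE, the globin chaperone Ahsp by -2.29 ± 0.64 SE and the blood group protein Ermap by -1.53 ± 0.43 SE. The list was called by camera (adjusted p = 7.92e-20, and adjusted p = 0.475 with an estimated correlation), and the exact permutation p of its score was 0.0571. Wild-type 1 had the highest globin share, 8.64% of counted reads, against 1.84% to 2.95% in the other wild-type embryos, and without it the log2 fold changes of Hba-x and Ahsp were -1.24 and -1.30. The score difference was -0.57 within title number 4 and -1.39 within title number 18.

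Neuronal genes had lower estimates in 34 of 37 cases, but 0 passed adjusted over the list alone and 0 over all genes. Tubb3, a tubulin of neurons, had 142 ± 80.4 CPM in knockout and 327 ± 90.2 CPM in wild-type embryos, and Crmp1, an axon growth protein, 72.9 ± 22.0 against 123 ± 18.1 CPM. Camera called the list (adjusted p = 5.51e-11, and adjusted p = 0.475 with an estimated correlation). Of 12 melanocyte genes, 1 fell adjusted over the list alone (0 over all genes): Pmel, the melanosome fibril protein, at 4.55 ± 1.73 against 9.75 ± 2.32 CPM (camera adjusted p = 0.006 for the list, and adjusted p = 0.475 with an estimated correlation). Macrophage genes had lower estimates in 23 of 26 cases (camera adjusted p = 3.02e-07, and adjusted p = 0.566 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. With the stage index as a covariate, the mean log2 difference turned from -1.11 to 0.11 for macrophage genes and shrank from -0.87 to -0.30 for neuronal and from -0.89 to -0.34 for melanocyte genes, and without knockout 4 that of macrophage genes was -0.63. The index shares genes with the neuronal list, Tubb3 among them, so the neuronal shrinkage is in part built in. The 2 most abundant macrophage members were Pf4 at 11.9 ± 7.16 against 19.6 ± 14.5 CPM and F13a1 at 7.71 ± 8.07 against 23.3 ± 14.3 CPM. The Pf4 values rested on wild-type 1, at 40.3 CPM against 8.11 to 18.5 CPM in the other wild-type embryos, and without it the log2 fold change of Pf4 was -0.086 in place of -0.71. That of F13a1, -1.60, ranged from -2.49 (without knockout 3) to -1.13 with single embryos left out. Over all alternatives it shrank to as little as -0.50.

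Gut and lung endoderm genes had higher estimates in 16 of 18 cases, and 7 rose adjusted over the list alone (0 over all genes). They included the endoderm transcription factor Foxa2 (log2 fold change 1.21 ± 0.30 SE), the tight junction gene Cldn6 (0.64 ± 0.20 SE), Spink1 and the posterior gut regulator Cdx1. The log2 fold change of Spink1 was 6.21, and 3.13 without knockout 3. That of Cdx1 was 2.50, and 1.96 to 3.13 with single embryos left out. Its lowest value over all alternatives was 0.61. Camera called the list (adjusted p = 9.42e-06, and adjusted p = 0.475 with an estimated correlation). Yolk sac endoderm genes rose in 10 of 20 cases adjusted over the list alone (0 over all genes), with S100g, Lrp2, Tmprss2 and Cubn at the smallest p. The rise of the list rested on knockout 3, where Cubn, the endocytic receptor cubilin, reached 177 CPM against 0.804 to 2.07 CPM in the other knockout embryos. Lrp2 depended less on it, with 106 CPM in knockout 3 and 87.4 CPM in knockout 4. The log2 fold change of Lrp2 was 1.73, and at least 1.42 with any single embryo left out. The list's mean log2 difference was 1.19 with all embryos, and its camera call (adjusted p = 0.00156, and adjusted p = 0.802 with an estimated correlation) was lost without knockout 3, when the mean log2 difference was -0.07. Hepatoblast genes had higher estimates in 23 of 24 cases, with 0 past the threshold adjusted over the list alone or over all genes (camera adjusted p = 0.028, and adjusted p = 0.816 with an estimated correlation), and their mean log2 difference was 0.60 with all embryos and -0.52 without knockout 3. That call was also lost without wild-type 3 (0.40) or wild-type 4 (0.29). The 13 mitochondrially encoded genes all had higher estimates, with 0 passing adjusted over the list alone or over all genes (camera adjusted p = 6.35e-05, and adjusted p = 0.566 with an estimated correlation). Wild-type 1 had 0.98% of its reads in these genes, against 2.01% to 2.78% in the other wild-type embryos, and without it the mean log2 difference was 0.25 in place of 0.55.

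Lysosomal and thiol genes were not called as groups in knockout against wild-type embryos. Of 39 lysosomal proteins, 20 had a positive fold change and 0 passed adjusted over the list alone or over all genes (camera adjusted p = 0.795). The 2 most abundant, Psap and Lamp1, had 267 ± 58.1 and 230 ± 40.3 CPM in knockout against 273 ± 23.0 and 237 ± 41.0 CPM in wild-type embryos. Of 29 genes of glutathione and thiol metabolism, 2 rose adjusted over the list alone (0 over all genes), Chac1 and Slc7a11, which are also ATF4 targets (camera adjusted p = 0.57 for the list).

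Across all 20771 genes, edgeR called 0 in knockout against wild-type embryos (smallest adjusted p = 0.106, for Chac1). At an unadjusted p under 0.05, 1730 genes were found, 882 with a higher and 848 with a lower estimate. DESeq2 called 122 genes, 90 higher and 32 lower, 38 of them predicted gene models, and limma voom with sample weights called 0. On simulated data, whose genes and embryos varied independently, DESeq2 called 50 of 20131 unchanged genes and edgeR 9. DESeq2's calls included Chac1, Mfsd12, Sesn2, Car4, a carbonic anhydrase, Plet1, Prdm1, the Hedgehog pathway gene Gli1, the kinesin Kif1a, Ucp2, Pmel and the atrial peptide gene Nppa. Predicted models such as Gm24305 and Gm23804 were also among its smallest p-values, and 4 of the 122 genes had symbols starting with Rnu.

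**Figure D2:**
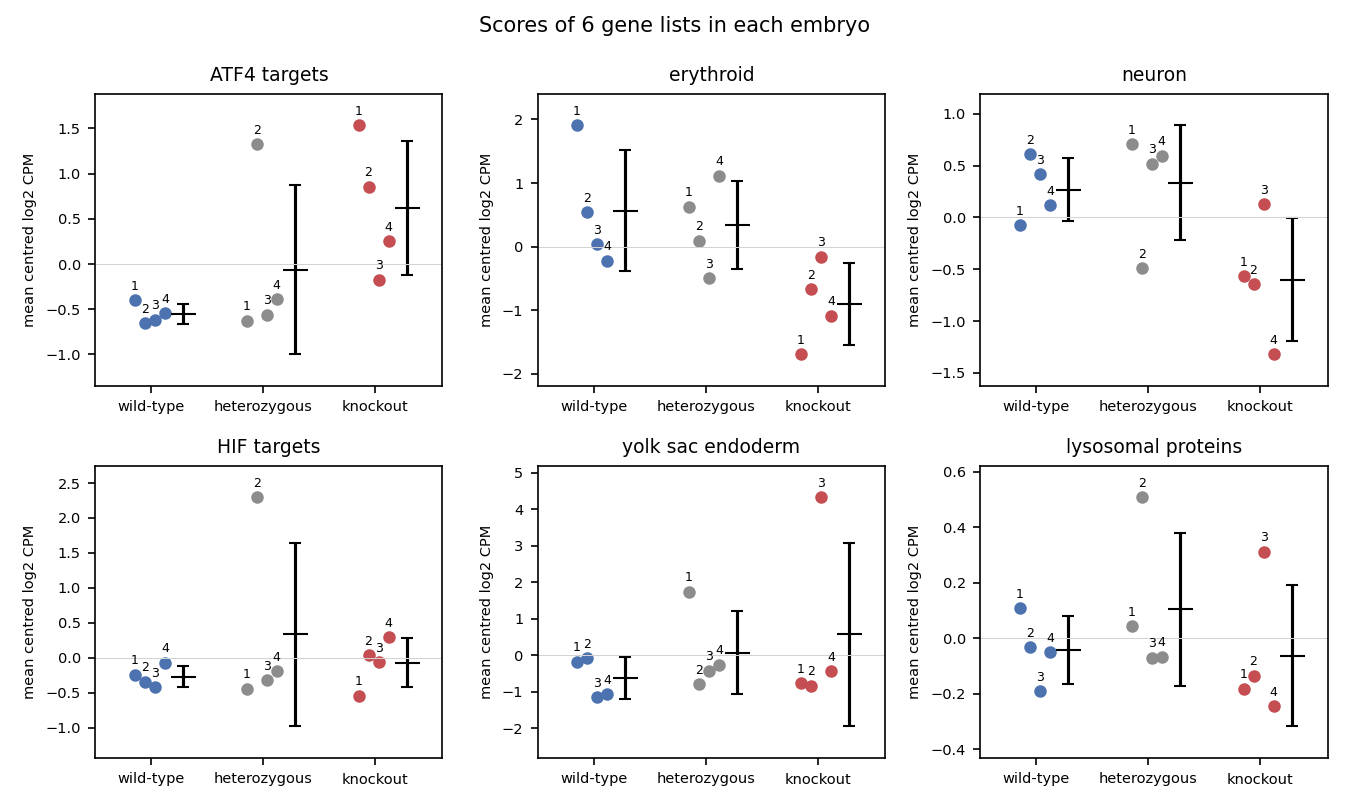
Scores of 6 gene lists (mean centred log2 CPM of the genes, linear axes) in each of the 12 embryos; points are embryos with their replicate number, and bars are the mean ± SD of 4 embryos. The library labelled heterozygous 2 had the highest HIF target score, 2.29, and knockout 3 the highest yolk sac score, 4.32.

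Against heterozygous embryos, knockout embryos again had more Chac1 (20.5 ± 13.4 against 0.842 ± 0.544 CPM, SD, n = 4; log2 fold change 4.61 ± 0.69 SE) and more Sesn2 (54.0 ± 33.3 against 14.9 ± 6.37 CPM). Kif1a, a neuronal kinesin, had 26.7 ± 9.62 against 58.3 ± 7.84 CPM, and Ap3b2, a neuronal adaptor subunit, 6.85 ± 0.783 against 12.3 ± 0.981 CPM. Of 36 ATF4 targets, 28 had a positive estimate and 2 rose adjusted over the list alone (0 over all genes), while 15 of 30 erythroid genes and 2 of 37 neuronal genes fell adjusted over their lists alone (0 over all genes). Camera called these 3 lists with adjusted p = 5.2e-06, 5.27e-16 and 6.75e-14, and with adjusted p = 0.761, 0.624 and 0.624 with an estimated correlation. The mean log2 difference of the ATF4 targets was 0.68, and it was 1.14 without the library labelled heterozygous 2 and 0.38 without knockout 1. Of 39 lysosomal proteins 32 had lower estimates (camera adjusted p = 0.00518, and adjusted p = 0.78 with an estimated correlation), and 0 passed adjusted over the list alone or over all genes. The lysosomal score was 0.51 in the library labelled heterozygous 2 and -0.07 to 0.044 in the other heterozygous embryos, and without that library the mean log2 difference went from -0.17 to -0.032 and the camera call was lost (adjusted p = 0.748). The call was also lost with the stage index as a covariate (mean log2 difference -0.061), and the difference was -0.27 without knockout 3 and -0.098 without knockout 4. EdgeR called 0 genes (smallest adjusted p = 0.253), with 1537 at an unadjusted p under 0.05. DESeq2 called 74, 44 higher and 30 lower, and limma voom called 0. The Y-linked gene Ddx3y was above 1 CPM in 3 of 4 knockout, 3 of 4 wild-type and 0 of 4 heterozygous embryos. Sex therefore differed along with every comparison that involves heterozygous embryos, including that of knockout against the mean of both other genotypes.

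Between heterozygous and wild-type embryos, genes of 4 of the 14 lists that camera called lay higher mainly through the library labelled heterozygous 2. Genes induced by low oxygen through HIF had higher estimates in 29 of 29 cases, yet 0 passed adjusted over the list alone or over all genes. The glycolytic enzymes Ldha and Tpi1 had 4245 and 2230 CPM in the library labelled heterozygous 2, against 972 to 1399 and 602 to 742 CPM in the other heterozygous embryos. All 36 ATF4 targets had a positive estimate, with 0 past the threshold adjusted over the list alone or over all genes. Camera called both lists (adjusted p = 5.27e-09 and 3.41e-07, and adjusted p = 0.978 for both with an estimated correlation). Without the library labelled heterozygous 2 the mean log2 difference of the HIF targets was -0.05. Lysosomal proteins had higher estimates in 32 of 39 cases (camera adjusted p = 0.000301, and adjusted p = 0.978 with an estimated correlation), with 0 past the threshold adjusted over the list alone or over all genes. Their mean log2 difference was 0.15 with all embryos and 0.011 without that library, that of the ATF4 targets 0.49 and 0.028, and both calls were lost without it. Unfolded protein response genes of the endoplasmic reticulum had higher estimates in 17 of 19 cases, with 0 past the threshold adjusted over the list alone or over all genes (camera adjusted p = 0.00871, and adjusted p = 0.978 with an estimated correlation), and their mean log2 difference was 0.17 with all embryos and -0.01 without that library. That call was also lost without heterozygous 1 (0.17) or wild-type 3 (0.12), with the title number as a block (0.13) and with Xist as a covariate (0.10). Hepatoblast genes had higher estimates in 23 of 24 cases and yolk sac genes in 17 of 20, and interferon response genes had lower estimates in 18 of 19, with 0 past the threshold adjusted over the lists alone or over all genes. Camera called these 3 lists (adjusted p = 0.000758, 0.0115 and 0.000436, and adjusted p = 0.978 for each with an estimated correlation) and still did so without the library labelled heterozygous 2, at mean log2 differences of 1.20, 0.98 and -0.34. The first 2 calls were lost without heterozygous 1 (0.33 and 0.12), without wild-type 3 (0.56 and 0.51) and without wild-type 4 (0.46 and 0.54), in place of 0.77 and 0.69. The interferon difference, -0.46, lost its call without wild-type 1 (-0.24) and with the title number as a block (-0.13). Gut and lung endoderm genes had higher estimates in 15 of 18 cases and endothelial genes in 20 of 29 (camera adjusted p = 0.00289 and 0.0137, and adjusted p = 0.978 for both with an estimated correlation), again with 0 past the threshold adjusted over the lists alone or over all genes, and both calls were lost without the library labelled heterozygous 2 (0.33 and 0.089, in place of 0.43 and 0.15). The endothelial call was also lost without heterozygous 3 (0.17), wild-type 1 (0.096) or wild-type 3 (0.15), with the title number as a block (0.12) and with Xist as a covariate (0.058). The other 5 called lists were mitochondrially encoded and neural progenitor genes, with mostly higher estimates, and macrophage, mesenchyme and surface ectoderm genes, with mostly lower ones (camera adjusted p = 0.00406 to 0.0419, and adjusted p = 0.978 for each with an estimated correlation), with 0 members past the threshold adjusted over the lists alone or over all genes. Without wild-type 1 the first 2 turned to -0.076 and -0.02, in place of 0.22 and 0.12, and the macrophage and surface ectoderm calls were lost (-0.066 and -0.15, in place of -0.34 and -0.38). Without heterozygous 3 the neural progenitor difference turned to -0.015 and the other 4 calls were lost. EdgeR called 0 genes (smallest adjusted p = 1), with 209 at an unadjusted p under 0.05. DESeq2 called 4, all lower and all Y-linked, and limma voom called 0.

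Chac1 was the only gene that passed edgeR's test over all genes when knockout embryos were set against the mean of both other genotypes. It rose by a log2 fold change of 4.87 ± 0.52 SE (edgeR adjusted p = 0.00652) and was higher in 4 of 4 knockout embryos than in any of the 8 others. Chac1 lies on chromosome 2 from 119181723 to 119184807 (GRCm39). Its levels were 33.1, 29.6, 4.28 and 14.96 CPM in knockout 1 to 4, and at most 1.5 CPM elsewhere. Within title number 4 the log2 difference of knockout from wild-type was 6.29, and within number 18 it was 2.42. At an unadjusted p under 0.05, 2198 genes were found, 1186 with higher and 1012 with lower estimates. DESeq2 called 269 genes and limma voom 4. EdgeR called 92 genes without knockout 3, 6 without the library labelled heterozygous 2, 2 without knockout 1 and 0 without wild-type 4 (Chac1 adjusted p = 0.0586). Chac1 also missed the threshold with the title number as a block (adjusted p = 0.0541), with numbers 4 and 18 alone and that block (0.14), with no low-count filter (0.0552) and with a ribosomal RNA covariate (0.12).

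The stage index, which rises with developmental age in these marker genes, was -1.01 ± 1.41 in knockout (SD, n = 4), 0.43 ± 0.57 in heterozygous and 0.58 ± 1.01 in wild-type embryos. Genes that are lower later, among them presomitic mesoderm genes, had positive estimates in knockout against wild-type embryos in 16 of 19 cases, and those that are higher later in 4 of 23 cases. Of the latter 7 fell adjusted over the list alone, of the former 0 passed, and 0 of either passed over all genes. Camera called both lists (adjusted p = 0.00108 and 3.02e-07, and adjusted p = 0.566 for both with an estimated correlation), and without knockout 4 their mean log2 differences were 0.58 and -0.65, in place of 0.89 and -1.01. With the title number as a block the second was -0.29. The index did not differ between knockout and wild-type beyond the spread between embryos (difference -1.59, exact permutation p = 0.143, and -0.99 without knockout 4), nor between knockout and heterozygous (-1.44, exact permutation p = 0.114). These tests disregard the title number. Heterozygous and wild-type embryos differed by -0.15, less than either SD. The 4 embryos of title number 18 lay between 0.55 and 1.75 and those of number 4 between -1.30 and 0.50, and the knockout embryo of number 15 lay lowest at -2.80. Within each number that held several genotypes, the knockout embryo was lowest. It had 0.55 in number 18, -1.30 in number 4, and -0.49 in number 14 against -0.23 in the library labelled heterozygous 2. A difference within title numbers was not tested.

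**Figure D3:**
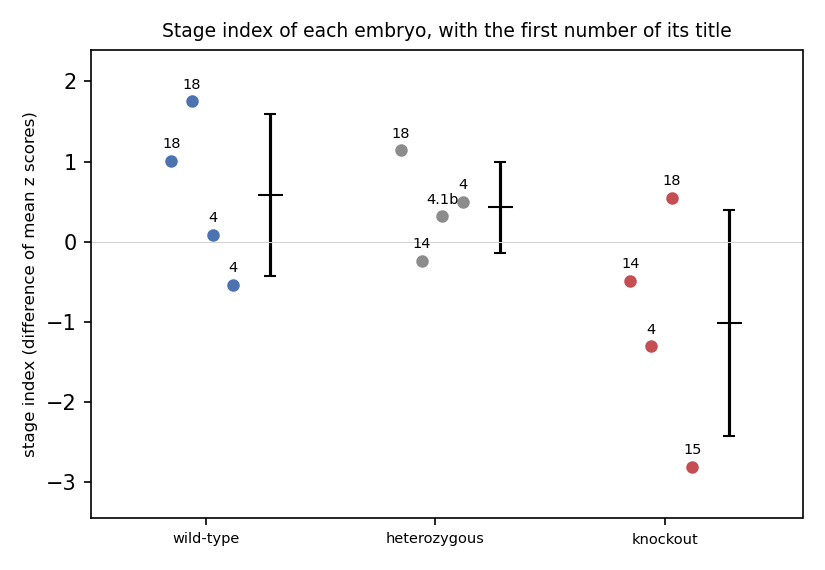
Stage index (difference of mean z scores, linear axis) of each of the 12 embryos by genotype, with the first number of its title beside each point; bars are the mean ± SD of 4 embryos. The lowest value, -2.80, is that of the knockout embryo of number 15.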

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

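The tests of explanations, for the library labelled heterozygous 2 and for knockout 3, were chosen after the results were seen, while the check for embryos that stood apart was fixed beforehand. Within each genotype of 4 embryos, values were checked for 1 embryo that stood far from the others. Of 207 checks 35 stood out, 17 of them in the library labelled heterozygous 2 and 7 in knockout 3. Chance marks about 1 in 20 independent checks, and since these checks share embryos and genes that vary together, and some genes were chosen after their values were seen, that rate is no measure of how many to expect here.

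The library labelled heterozygous 2 had the highest value of its genotype for many ATF4 targets. Asns reached 720 CPM, against 55.2 to 97.7 CPM in the other 3, Psat1 914 CPM, Slc7a5 165 CPM, Slc7a3 110 CPM, Cth 105 CPM, Stc2 74.3 CPM, Slc7a11 27.8 CPM, Atf5 83.2 CPM and Atf3 14.9 CPM. The HIF targets Ldha and Tpi1 stood at 4240 and 2230 CPM. Its list scores stood apart at 1.33 for ATF4 targets and 2.29 for HIF targets, and at -0.49 for neuron, -0.82 for melanocyte and -0.78 for mitochondrially encoded genes. Ap3b2 was low there, at 10.8 CPM.

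That library also had Mfsd12 at the knockout level, for which one candidate explanation is a knockout embryo under a heterozygous label. On 100 genes that parted knockout from the other embryos when it was held out, it scored 0.783, where 0 is the mean of the other genotypes and 1 that of knockout embryos. Held-out knockout embryos scored 0.07 to 0.98 and the 7 other embryos -0.02 to 0.20, so the library lay inside the knockout range and above the 7 other embryos. The score did not pick out every knockout embryo, since knockout 2 (0.157) and knockout 3 (0.065) lay below wild-type 4 (0.203). The library labelled heterozygous 2 was also counted among the other genotypes when the knockout embryos were scored. The 2 ranges overlapped and Chac1, at 1.5 CPM, lay below all knockout embryos, so the label stays open. A disturbed library stays open as well: 7.16% of the genes at a similar level were at least as far below the other heterozygous embryos as Mfsd12 was.

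Knockout 3 had yolk sac genes far above the other knockout embryos. Its list score was 4.32, with Afp at 3320 CPM, Cubn at 177 CPM, Tmprss2 at 39.4 CPM, S100g at 36.5 CPM and Spink1 at 17.9 CPM. Of genes that reached 1 CPM in an embryo, 12 of 13 that only the yolk sac list holds and 12 of 18 that only the hepatoblast list holds were highest in this embryo (Fisher's exact test, two-sided, p = 0.191, across genes, which are not independent). The hepatoblast score was also highest there, at 3.56 against 1.61 at most in the other embryos, while the single liver product Alb ranked 5 of 12 at 10.3 CPM, so yolk sac tissue in the sample and more liver cannot be told apart and either may contribute. A biological explanation was not tested, since 1 embryo of the genotype showed it.

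Heterozygous 1 had 8.03 CPM of Cubn, 3.47 CPM of Spink1 and 2.96 CPM of S100g, the highest of its genotype, and 2.22% of its reads in rows that take ribosomal RNA reads. Wild-type 1 stood apart in red blood cell genes, with globins at 8.64% of reads, Hba-x at 18900 CPM, Slc4a1 at 798 CPM, Ahsp at 200 CPM and Ermap at 84.1 CPM. In knockout embryos, Gli1 was lowest in knockout 3 at 38.9 CPM and Ap3b2 lowest in knockout 4 at 5.69 CPM, and Tpi1 lowest in knockout 1 at 351 CPM.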

How the results depend on the processing

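The settings without the library labelled heterozygous 2 and knockout 3, with a ribosomal RNA covariate, with other list methods and with other scalings of the lists were chosen after seeing the data. The cause of the moves below was not tested, except that leaving out embryos or using fewer embryos changes the fit by construction. Mfsd12 kept its direction and its side of the threshold in knockout against wild-type embryos in all 25 alternatives (log2 fold change -2.11 to -1.45) and in heterozygous against wild-type in all 25 (-1.31 to -0.70). In knockout against heterozygous, its p rose above the threshold with the Xist covariate (log2 fold change -0.82) and with the stage index covariate (-0.45). The stage index difference, -1.59, kept its direction and missed the threshold in all 11 alternatives (-2.11 to -0.70).

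Counts of genes called in knockout against wild-type, knockout against heterozygous, heterozygous against wild-type and knockout against the mean of both were 0, 0, 0 and 1. DESeq2 gave 122, 74, 4 and 269, title numbers 4 and 18 alone with the number as a block 13, 1, 1 and 15, and the fit without the library labelled heterozygous 2 and knockout 3 gave 19, 33, 0 and 441. The block over all title numbers gave 2 in the first and 3 in the last, S100g and Napsa in both and Slc7a1 in the last. In the last, limma voom gave 4, the stage index covariate 13, and no low-count filter and the ribosomal RNA covariate 0 each. With each embryo left out the counts were 0 to 1, 0 to 1, 0 and 0 to 92. Chac1 was the 1 gene called without knockout 3 in both of the first comparisons, and Car4 the 1 gene called in the first without knockout 1. The labels give no replicate numbers to pair by, and the title number served as the block. Of 11 pairs of embryos with 1 title number and different genotypes, 7 deviated together with a correlation over 0.1 (median 0.117), against 9 of 37 pairs of different numbers (median -0.056). The 5 pairs of number 18 lay at 0.332 to 0.576 and the 5 of number 4 at 0.03 to 0.117.

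Lists called were 15 in knockout against wild-type, 16 in knockout against heterozygous and 14 in heterozygous against wild-type, and 0 in each with an estimated correlation and by exact permutation of the scores. The permutation count says little, since a list could pass only if most lists reached the smallest possible p. Without single embryos they were 13 to 19, 9 to 20 and 8 to 14, and 9 in the last without the library labelled heterozygous 2 and knockout 3. Chac1 passed the threshold against the mean of both genotypes in 19 of 24 alternatives (adjusted p from 2.44e-18 to 0.14, log2 fold change 4.55 to 5.43).

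Directions turned as follows (mean log2 difference). With the stage index covariate, knockout against wild-type gave 0.11 for macrophage, 0.15 for megakaryocyte and 0.11 for stage-higher genes, and knockout against heterozygous gave 0.34, 0.08 and 0.007 for the same lists and -0.008 for stage-lower genes. The stage-higher and stage-lower genes make up the index, so their own moves follow from the covariate. Leaving out knockout 3 turned hepatoblast (-0.52 to 1.20 over single embryos left out) and yolk sac genes (-0.066 to 1.66), and without the library labelled heterozygous 2 as well they stood at -0.53 and -0.045. Leaving out the library labelled heterozygous 2 turned HIF targets in knockout against heterozygous (-0.65 to 0.25) and in heterozygous against wild-type (-0.049 to 0.86), and the unfolded protein response in the latter (-0.01 to 0.27). Without both embryos these stood at 0.26, -0.047 and -0.008. In heterozygous against wild-type, leaving out wild-type 1 turned mitochondrially encoded genes (-0.076 to 0.47) and, like heterozygous 3, neural progenitor genes (-0.02 to 0.35). Single genes in knockout against wild-type turned too. Alb stood at 1.11 and Pf4 at 0.084 with the stage covariate, and Pf4 at 0.047 with numbers 4 and 18 alone. Afp ranged from -0.76 to 4.65, turning without knockout 3, and stood at -0.76 without both embryos. Psap ranged from -0.19 to 0.042 and Lamp1 from -0.14 to 0.051 with single embryos left out. Tpi1 ranged from -0.176 to 0.179, turning without knockout 1 and without wild-type 1, and gave 0.17 with numbers 4 and 18 alone and 0.005 with the ribosomal RNA covariate. Ldha gave -0.183 with limma voom and -0.327 with the stage covariate. Lamp1 also gave 0.055 with limma voom, 0.049 with the block, 0.13 with numbers 4 and 18 alone, 0.17 with the stage and 0.061 with the ribosomal RNA covariate. The other results, single genes and lists, gave 1801 values of unchanged direction and side, 36 that passed the threshold anew and 152 that no longer passed it. Since 0 of these single genes passed in the main fit, none could be among the 152. For them an unchanged side means only that they still missed the threshold.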

Other observations

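The tests of the ATF4 targets with covariates and the counts over other splits of the embryos were set out only after their results were seen, except that the splits within title numbers were set out after the first splits were seen and before their own result, and the permutation of list scores was added after seeing the data, while the gene lists and the camera test were fixed beforehand. Further gene groups were compared between knockout and wild-type embryos. Of 28 p53 targets, 19 had a positive estimate and 1, Sesn2, rose adjusted over the list alone (0 over all genes). Their score was 0.056 ± 0.10 in knockout against -0.079 ± 0.035 in wild-type embryos (SD, n = 4; exact permutation p = 0.0286, the smallest possible, and 0.4 after adjustment over the lists), and camera did not call the list (adjusted p = 0.304, and adjusted p = 0.811 with an estimated correlation). Smooth muscle and pericyte genes had lower estimates in 11 of 14 cases, with 0 past the threshold adjusted over the list alone or over all genes and no camera call (adjusted p = 0.0653). Their score was -0.24 ± 0.24 in knockout, 0.11 ± 0.16 in heterozygous and 0.13 ± 0.18 in wild-type embryos, and the exact permutation p of knockout was 0.0286 against each, or 0.6 and 0.4 after adjustment over the lists. Somite and presomitic mesoderm genes had positive estimates in 16 of 22 cases and skeletal muscle genes in 6 of 23, with 0 members of either past the threshold adjusted over the list alone or over all genes. Camera called both (adjusted p = 0.00605 and 0.00456, and adjusted p = 0.566 for both with an estimated correlation). The somite call was lost without knockout 2 and the muscle call without knockout 3, at mean log2 differences of 0.59 and -0.52, in place of 0.71 and -0.53, and without knockout 4 the muscle genes differed by -0.30. With the stage index as a covariate the somite difference shrank to 0.19 and its call was lost, and the muscle difference shrank to -0.21 and was still called. The index shares genes with both lists, so these moves are in part built in and do not show that stage accounts for the differences. Cholesterol synthesis genes had lower estimates in 20 of 25 cases and megakaryocyte genes in 12 of 17, with 0 members past the threshold adjusted over the lists alone or over all genes (camera adjusted p = 0.00457 and 0.0489, and adjusted p = 0.614 and 0.811 with an estimated correlation). The first call was lost without knockout 1 (-0.068, in place of -0.17) or wild-type 4 (-0.12). The second was lost without knockout 4 (-0.097, in place of -0.42), wild-type 1 (-0.18), knockout 1 (-0.33) or the library labelled heterozygous 2 (-0.42), and was -0.68 without knockout 3.

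Single genes with small unadjusted p, chosen after their values were seen, included Gli1 at 46.9 ± 5.38 CPM in knockout and 29.8 ± 4.37 CPM in wild-type embryos. Prdm1, a transcriptional repressor, had 7.69 ± 2.40 against 3.30 ± 0.833 CPM, Car4 17.8 ± 15.8 against 2.32 ± 0.24 CPM and the neutral amino acid transporter Slc1a4 75.9 ± 36.6 against 33.4 ± 3.01 CPM. Car4 had 39.5 CPM in knockout 4 and 2.27 to 17.4 CPM in the other knockout embryos, the lowest inside the wild-type range of 2.13 to 2.64 CPM. Nppa had 18.5 ± 7.68 against 47.8 ± 12.4 CPM and the mitochondrial carrier Ucp2 42.3 ± 17.6 against 133 ± 81.3 CPM. Adjusted p was 0.537 for each in edgeR.

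The higher ATF4 target score of knockout embryos, 1.16 ± 0.55 (SE) above wild-type in a linear model of the mean z score of its genes over the 12 embryos, was set against 3 explanations. Title number was not among these explanations. The limit of 2 standard errors used to judge them was set after the results were seen. With the HIF target score in the model the difference was 1.05 ± 0.47. It was 1.35 ± 0.38 without the library labelled heterozygous 2, from which most of the spread of that score comes. These values argue against low oxygen, as read from HIF targets, as the whole source of the difference. A poor state of the tissue of another kind was not tested. A difference in developmental stage stays open, with a difference of 0.943 ± 0.70 once the stage index was included, between 1 and 2 standard errors from 0 (1.15 ± 0.52 without that library). Library composition also stays open, with 1.17 ± 0.69 once the ribosomal RNA rows, highest in knockout 4 at 8.36% of reads, were included (1.12 ± 0.50 without that library). Without that library both differences lay more than 2 standard errors from 0, so the contrast with low oxygen rests on it. An effect of the genotype may therefore be 1 of several sources of the difference.

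Other splits of the same embryos were tested as a check on chance. For the call of Chac1 against the mean of both genotypes, 1 gene was called in the real grouping and 0 in any other of 100 drawn splits, so that 1 of the 100 gave as many. These splits disregard the title number, and embryos of number 18 deviated together (correlations 0.332 to 0.576), so they cannot settle the role of chance. Among 100 splits that shuffled the genotypes only within each title number, in which knockout 4 stayed a knockout embryo, 6 gave as many (highest other 2), so that chance is not excluded for the call. For the 3 pairs of genotypes edgeR called 0 genes in the real split, which any of the 35 splits must match, so these counts say nothing about chance. The highest other count was 0 in knockout against wild-type, 175 in knockout against heterozygous and 1187 in heterozygous against wild-type. Genes at an unadjusted p under 0.05 numbered 1730, 1537 and 209, and 6, 9 and 35 of 35 splits gave as many (highest others 3545, 3388 and 5073). Against the mean of both genotypes 2198 genes were found, and 16 of 100 splits gave as many (highest other 3216). The lists called, 15, 16 and 14, were matched by 15, 12 and 14 of 35 splits (highest others 24, 20 and 19), so that chance is not excluded for these counts. The split with 1187 genes set heterozygous 1, the library labelled heterozygous 2, wild-type 1 and wild-type 2 against the rest, and points to a structure of the samples other than genotype: 3 of these 4 embryos carry title number 18. With title number as a block edgeR called 2, 0 and 0 genes for the 3 pairs, and with numbers 4 and 18 alone 13, 1 and 1. The first 2 were S100g and Napsa, and S100g was high in knockout 3 (36.5 CPM). Numbers 4 and 18 held only knockout 2 and knockout 3 of that genotype. The 13 included Apoa4 and S100g as well as Mfsd12, Slc7a3 and Stc2. Apoa4 was the call in both other pairs, at 275 CPM in knockout 3 and 29.7 CPM in heterozygous 1. The split with 175 genes exchanged knockout 3 for the library labelled heterozygous 2.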
